A study of Homo sapiens with 14 samples.

How the data were processed

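Polyadenylated RNA from MCF7, an established human breast cancer cell line that expresses the oestrogen receptor, was isolated with a column kit and made into stranded mRNA libraries, per the labels. The 14 libraries fell into 6 groups by genotype. The control group and each of 3 pools labelled MED1 knockout (KO1, KO2 and KO3) had 2 libraries. The groups with ectopic wild-type (WT) MED1 and with ectopic 6KR MED1, a mutant form, had 3 libraries each. Per the file headers, the WT and 6KR cells also carry a KO mark, and the series describes such cells as having the endogenous MED1 depleted. The labels number the replicates without saying whether they came from separate cultures. The p-values of the main fits thus measure the spread between libraries of the same group, part of which may be technical.

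The authors deposited 2 tables of gene counts, 1 for the control and knockout libraries and 1 for the WT and 6KR libraries. The deposited values were read to be expected counts per gene, not scaled to depth. They were whole numbers already, so rounding changed nothing. The submitters' processing notes name Salmon 0.8.2, DESeq2 and the genome build hg38. The notes do not say which step each tool served, nor which annotation or filter was used. Each table listed 25186 genes by Entrez identifier, of which 4890 in the knockout table and 4174 in the 6KR table were at 0 in every library. Symbols and positions came from a RefSeq gene table on GRCh38.p14, which matched 25081 identifiers (99.6%). The total count per library ran from 7818433 to 10809391 in the knockout table and from 27518481 to 39038220 in the 6KR table. The 10 most abundant genes held between 4.73% and 5.35% of each library. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom from 1.60 to 26.9 over genes with a summed count of at least 20. No library was left out of the main fits.

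The tables were fitted separately in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test. Counts were scaled by the trimmed mean of M values (TMM), after keeping genes with edgeR's filter at a minimum count of 10 and a minimum total of 15. This left 13298 genes in the knockout table and 14839 in the 6KR table. Each fit had 4 residual degrees of freedom, and the biological coefficient of variation was 5.57% and 7.77%. Group means were compared by contrasts: the average of the 3 pools against control, each pool against control, the pools against each other, and 6KR against WT. A joint test asked whether the 3 pools differed from each other. Each pool had its own mean, so differences between pools did not enter the spread behind the p-values. This also holds where an SD is given over all knockout libraries. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Levels are counts scaled to library size (CPM) after TMM scaling within a table, given as mean ± SD. Fold changes are on the log2 scale.

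Genes were named by a rule. It took MED1, the 10 largest rises and 10 largest falls per main comparison (3 for single pools and pool differences) among genes with an official symbol past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries. It also took up to 4 members of each gene list with the smallest adjusted p, and a fixed group of genes given whether or not they passed. Gene lists numbered 39, with 1012 symbols of 971 genes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The list of mitochondrially encoded genes had no tested member and was not analysed here, so 38 lists were tested. The genes called in the pool average were also tested as sets in the 6KR table with fry, with p adjusted over the 2 sets, which was decided after the unadjusted p had been seen. The groups, comparisons, thresholds, lists, naming rule and most alternatives were fixed before the data were examined.

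Alternatives tried were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, library totals with no further scaling, no filter or a mean of at least 5 CPM, an adjusted p of 0.01, a log2 fold change of at least 1, replicate number as a block, pool sums, fits without a pool or with only the groups compared, and fits without each of the 14 libraries in turn. In another fit all knockout libraries formed a single group, without a mean per pool. A fit that left a group with 1 library assumed that it varied like the others. Offsets that removed a smooth trend on GC content and transcript length from each library were fitted with mgcv 1.9.3, using transcripts of GENCODE release 29. GC content was known for 99.0% of tested genes in the knockout table and 98.7% in the 6KR table. This correction and the fits on library totals were added after the data were seen.

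The fits were tested on simulated data with known changes. The pool average recovered 58.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 7.51% of its calls were unchanged genes. For a single pool the same shares were 49.3%, 77.6%, 92.4% and 7.01%. The joint test of the pools recovered 67.2%, 83.6% and 95.5%, and 11.4% of its calls were unchanged genes. For 6KR against WT the shares were 73.1%, 88.1% and 98.5%, with 4.42% of calls unchanged genes. Of 40 simulated lists of 30 genes, the 5 raised by 1.3-fold were all recovered in both tables. By fry, 1 unchanged list was also called in the knockout table. Genes were drawn independently, so false calls of lists whose members vary together were not tested. In the tests on single genes each size of change was given to 66 or 67 genes. In all these were fewer than the genes called in the real pool average or in 6KR against WT. The adjusted p depends on how many genes change, so recovery in the real data may differ. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.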

Results

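RNA sequencing measured polyadenylated transcripts in 14 libraries of MCF7 cells, namely controls, pools labelled MED1 knockout and cells with ectopic MED1. MED1 is a subunit of the Mediator complex, which links transcription factors to RNA polymerase II. The knockout table held 2 control libraries and 2 libraries from each of 3 pools labelled MED1 knockout (KO1, KO2 and KO3). The 6KR table held 3 libraries of cells with ectopic WT MED1 and 3 of cells with the mutant form labelled 6KR. Total counts were 9491338 and 8132945 in the control libraries, 10614782 and 8707142 in KO1, 8829010 and 8211252 in KO2, and 10809391 and 7818433 in KO3. They were 31972278, 32312605 and 33100859 in the WT libraries and 32551342, 39038220 and 27518481 in the 6KR libraries. Of 25186 listed genes, 13298 were tested in the knockout table and 14839 in the 6KR table.

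The series concerns MED1 acetylation in oestrogen receptor positive breast cancer cells, and its first RNA comparison asks what changes when MED1 is knocked out. The MED1 transcript (Entrez 5469, protein coding, chromosome 17 from 39404285 to 39451263 on GRCh38.p14) was lower than control in the libraries labelled KO2 and KO3 and not in those labelled KO1. It stood at 89.5 and 97.5 CPM in the control libraries (93.5 ± 5.68, SD, n = 2). The libraries labelled KO1 had 101 and 93.7 CPM (97.4 ± 5.13, n = 2, log2 fold change 0.06, adjusted p = 0.654). KO2 had 68.5 and 73.4 CPM (71.0 ± 3.46, n = 2, -0.40, adjusted p = 0.00245), and KO3 had 60.3 and 65.1 CPM (62.7 ± 3.41, n = 2, -0.58, adjusted p = 0.000216). The average of the 3 pools lay -0.30 (SE 0.07) below control, with adjusted p = 0.00292, and 0.0844 without control replicate 2. In the 6KR table MED1 stood at 698, 882 and 855 CPM with WT MED1 (812 ± 99.6, n = 3) and at 1274, 1371 and 1279 CPM with 6KR MED1 (1308 ± 54.7, n = 3). This was a 1.61-fold difference (log2 fold change 0.69, SE 0.09, adjusted p = 0.00756), no longer past the threshold without 6KR replicate 1 (0.0603) or replicate 3 (0.0556). A count over the whole gene measures neither the edit, whose site the labels do not give, nor the protein, and it does not separate ectopic from endogenous transcripts.

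**Figure D1:**
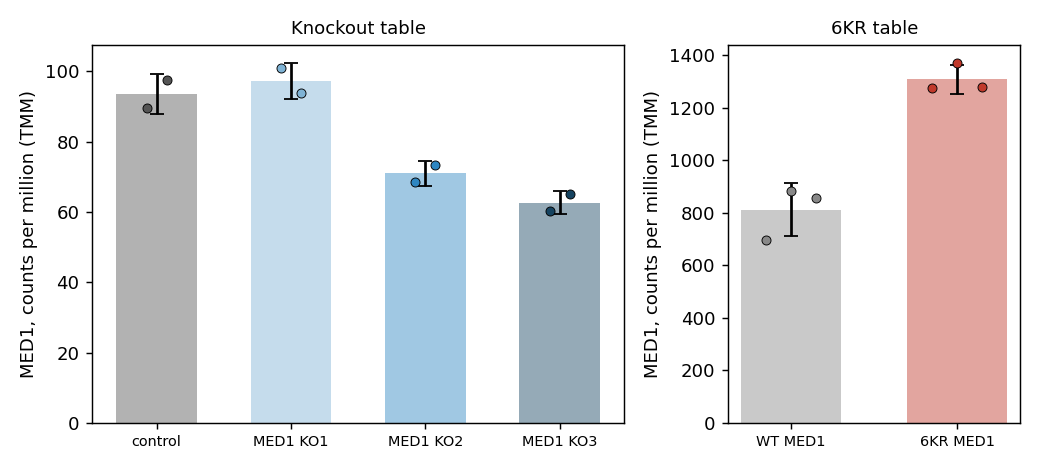
MED1 transcript level in CPM after TMM scaling, per library (points) with the mean (bar) and SD (error bar) of each group, in the knockout table and in the 6KR table. The libraries labelled KO1 (101 and 93.7 CPM) lie beside the controls (89.5 and 97.5 CPM), and the 6KR libraries (1274 to 1371 CPM) lie above the WT libraries (698 to 882 CPM).

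Genes that drive cell division fell together in the knockout pools. All 35 tested G2/M and mitosis genes were lower than control on the average of the pools (35 adjusted over the list alone), with a median log2 fold change of -0.69. TOP2A, the topoisomerase that untangles chromosomes, fell from 648 ± 9.99 CPM (n = 2) to 363 ± 27.4 CPM (n = 6, log2 fold change -0.83, SE 0.06, adjusted p = 1.16e-07). The mitotic kinase gene AURKA fell from 205 to 118 CPM (-0.80). CCNA2, for cyclin A2, fell from 112 to 62.7 CPM (-0.84) and CDK1 from 172 to 104 CPM (-0.73). Of 39 DNA replication and G1/S genes, 37 fell and 0 rose (38 and 0 adjusted over the list alone, median -0.54). Among them were RRM2 and TYMS, which make DNA precursors (-0.78 and -0.76), RFC3 (-0.65) and MCM3, a subunit of the replicative helicase (-0.54). Of 30 DNA repair genes, 21 fell and 0 rose (22 and 0 adjusted over the list alone, median -0.45). CHEK1 was at -0.78, BRIP1 at -0.63, FANCD2 at -0.60 and FANCI at -0.59. As lists these passed camera with adjusted p = 3.24e-67 for G2/M, 1.91e-35 for replication and 2.53e-16 for repair. They had adjusted p = 0.0158, 0.0280 and 0.0663 with an estimated correlation, so the repair call was lost.

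Oestrogen-responsive and immediate early genes were lower as well. Of 38 oestrogen-induced genes, 20 fell and 2 rose (20 and 2 adjusted over the list alone, median -0.22, adjusted p = 1.60e-09, adjusted p = 0.0342 with an estimated correlation). TFF1, a classic oestrogen receptor target, fell from 986 ± 77.3 CPM (n = 2) to 461 ± 52.7 CPM (n = 6, log2 fold change -1.10, SE 0.07, adjusted p = 6.82e-08). XBP1, a transcription factor of luminal breast cells, fell from 1029 ± 19.9 to 516 ± 21.5 CPM (-0.99, SE 0.05, adjusted p = 4.35e-09). ESR1, the oestrogen receptor itself, fell by 0.32 (526 ± 9.24 to 421 ± 13.2 CPM, adjusted p = 7.24e-05) and GREB1 by 0.31 (adjusted p = 0.000350). PGR stood at 43.8 and 43.4 CPM (adjusted p = 0.906). MYC was at -0.47 (adjusted p = 0.00254, 0.0777 without control replicate 2) and CCND1 at -0.19 (0.00963, 0.0943 without control replicate 1 and 0.0963 without control replicate 2). Among 25 immediate early genes 13 fell and 1, FOSL2, rose (14 and 1 adjusted over the list alone, median -0.37, adjusted p = 4.75e-05, adjusted p = 0.0663 with an estimated correlation). EGR1 fell from 40.2 ± 4.66 to 13.6 ± 3.09 CPM (-1.59, adjusted p = 3.04e-07), FOS from 9.65 to 3.46 CPM (-1.49) and EGR3 from 4.06 to 1.14 CPM (-1.85).

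Among the 10 largest falls were also CXCR4, a chemokine receptor (-1.53, adjusted p = 1.14e-07), and AREG, an EGF receptor ligand (-1.34, adjusted p = 4.39e-06). TIMP3, an inhibitor of matrix metalloproteinases, fell 2.67-fold from 177 ± 5.77 to 66.2 ± 2.15 CPM (-1.42, SE 0.05, adjusted p = 6.80e-10). BMP7, a secreted growth factor, fell from 111 to 48.2 CPM (-1.21), and PDE9A (-1.22), KDELR3 (-1.21), MFAP5 (-1.18) and ANP32E (-1.16) completed them. In lipid metabolism the desaturase genes SCD (1545 ± 2.06 to 928 ± 36.6 CPM, -0.74) and FADS1 (64.6 to 32.0 CPM, -1.01) fell, while ACSL1 rose (0.74).

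Rises were led by RIPOR3 (1.60, SE 0.18, 3.54 to 10.9 CPM, adjusted p = 1.43e-05), H4C8 (1.58, SE 0.13, 8.86 ± 0.278 to 26.5 ± 2.52 CPM, adjusted p = 7.17e-07), H2BC4 (1.48), ANXA3 (1.46), VASN (1.45), SSPOP (1.39) and AHRR, the repressor of the aryl hydrocarbon receptor (1.38). GPM6A (1.58, adjusted p = 0.00779), KLF15 (1.58, 0.00314) and PRRG3 (1.54, 0.00387) lost their calls without a control but kept their sign, with log2 fold changes of 1.32 to 1.83, 1.32 to 1.74 and 1.17 to 2.10 over the 8 fits without 1 library. GPM6A reached 0.0786 and 0.105 without control replicate 1 or 2, KLF15 0.0685 and 0.0512, and PRRG3 0.0915 without replicate 2. Of 10 replication-dependent histone genes, whose near copies share reads so that single members are uncertain, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.57, adjusted p = 3.27e-09, adjusted p = 0.0342 with an estimated correlation). Their summed level rose from 266 ± 0.191 to 431 ± 42.3 CPM. Among 28 autophagy and lysosome genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 5.49e-05, adjusted p = 0.151 with an estimated correlation), including the kinase gene ULK1 from 43.3 to 77.1 CPM (0.80). Of 30 p53 targets, 12 rose and 4 fell (14 and 4 adjusted over the list alone, adjusted p = 0.00388, adjusted p = 0.113 with an estimated correlation). TP53INP1 rose from 101 ± 1.90 to 216 ± 9.14 CPM (1.09, adjusted p = 3.45e-08) and CDKN1A, which encodes the cell cycle inhibitor p21, from 74.3 to 110 CPM (0.56, adjusted p = 0.000234). Keratins and cell junction genes rose in 8 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone, adjusted p = 0.0110, adjusted p = 0.142 with an estimated correlation), led by KRT80 (64.5 to 130 CPM, 1.01). The call on this list was lost after GC and length correction (adjusted p = 0.0501 by camera). Aryl hydrocarbon receptor targets rose in 4 of 8 cases (4 adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.159 with an estimated correlation). The largest subunit of RNA polymerase II, POLR2A, rose from 546 ± 35.4 to 868 ± 39.6 CPM (0.67, adjusted p = 1.24e-06).

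Genes of protein synthesis and folding were modestly lower. Of 51 cytosolic ribosomal proteins, a class with many near copies, 30 fell and 0 rose (35 and 0 adjusted over the list alone, median -0.18, adjusted p = 2.50e-09, adjusted p = 0.181 with an estimated correlation). Ribosome biogenesis genes fell in 13 of 30 cases and rose in 1 (16 and 1 adjusted over the list alone, adjusted p = 0.000655, adjusted p = 0.151 with an estimated correlation), with NPM1 at -0.49 and NCL at -0.32. Heat shock chaperones fell in 12 of 20 cases and rose in 2 (13 and 3 adjusted over the list alone, adjusted p = 0.000119, adjusted p = 0.154 with an estimated correlation), with HSPA8 from 3616 to 2704 CPM (-0.42) and HSP90AA1 at -0.47. Endoplasmic reticulum stress genes (7 fell and 5 rose of 24, or 9 and 5 adjusted over the list alone) had adjusted p = 0.0110, and adjusted p = 0.142 with an estimated correlation. ATF4 and amino acid response genes (12 fell and 2 rose of 30, also 12 and 2 adjusted over the list alone) had adjusted p = 0.0261, and adjusted p = 0.260 with an estimated correlation. NRF2 oxidative stress genes (8 fell and 2 rose of 29, or 8 and 3 adjusted over the list alone) had adjusted p = 0.0374 (0.0589 without control replicate 1), and adjusted p = 0.273 with an estimated correlation. The NRF2 list also fell short on library totals alone (adjusted p = 0.0644 by camera). Interferon-stimulated genes (11 fell and 2 rose of 39, also 11 and 2 adjusted over the list alone) had adjusted p = 0.0261, 0.0501 after GC and length correction, and adjusted p = 0.151 with an estimated correlation. This average joins pools that moved in opposite directions.

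The other 21 lists tested did not pass on the pool average. Mediator subunits had 4 of 33 members higher and 2 lower, MED1 among the latter (4 and 2 adjusted over the list alone, adjusted p = 0.880), and MED24 was at -0.01 (adjusted p = 0.941). RNA polymerase II subunits and pausing factors had 5 of 24 higher and 4 lower (5 and 4 adjusted over the list alone, 0.291). Luminal lineage genes had 6 of 19 higher and 5 lower (7 and 6 adjusted over the list alone, 0.880), with ELF3 at 0.72 and GATA3 at -0.35. Adjusted p was 0.609 for basal and mesenchymal genes, 0.142 for metallothioneins, 0.289 for hypoxia response genes, 0.385 for glycolysis enzymes, and 0.114 for cholesterol synthesis genes. It was 0.260 for fatty acid synthesis genes, 0.278 for antigen presentation genes, 0.880 for NF-kB and inflammatory genes, and 0.403 for YAP and TGF-beta targets. Nuclear receptors and partners had 0.291, and acetyltransferases and deacetylases 0.678 (EP300 at adjusted p = 0.993 and SIRT1 at 0.988). It was 0.777 for pro-apoptotic and anti-apoptotic genes, 0.733 for extracellular matrix genes, 0.678 for nuclear-encoded oxidative phosphorylation genes and 0.347 for neighbours of MED1 on chromosome 17. Within these, BMF, a pro-apoptotic gene, rose from 10.9 to 25.4 CPM (1.20), THBS1, a matrix glycoprotein gene, fell from 553 to 314 CPM (-0.82), and ERBB2, a neighbour of MED1, rose from 152 to 211 CPM (0.47). Markers of other cell types also did not pass, with adjusted p = 0.0871 for fibroblasts, 0.670 for blood and immune cells and 0.777 for endothelium. The median, mean and test differed in sign for Mediator, luminal, fatty acid, YAP and TGF-beta, apoptosis, extracellular matrix and oxidative phosphorylation genes.

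In all, 3720 of 13298 genes passed on the pool average, 1862 higher and 1858 lower, with a median size of 0.38 on the log2 scale. Of these, 136 were at least 2-fold higher and 57 at least 2-fold lower. All told, 3450 of the 3720 had all 6 knockout libraries on 1 side of both controls, against 37.8% of all tested genes and 7.14% by chance. Passing the threshold with so few libraries favours such genes, so this is not separate support. A fit with all knockout libraries as a single group, where differences between pools entered the spread, passed 3437 genes. Pool sums gave 3795. With library totals alone 3945 genes passed and 63.2% of them were higher, against 50.1% with TMM scaling. The count fell to 1364 without control replicate 1 and to 1962 without control replicate 2. Of 145 named genes that passed, 99 did so in each of the 8 fits that left out 1 library and all 145 kept their sign.

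Each pool was also set against control on its own, to ask whether the pools changed alike. The division and oestrogen programmes moved in all 3 of them. All 35 G2/M genes fell in KO1, KO2 and KO3 (35 in each adjusted over the list alone, medians -0.67, -0.74 and -0.63, adjusted p = 0.0186, 0.0262 and 0.0121 with an estimated correlation). Oestrogen-induced genes fell in 17, 18 and 20 of 38 cases and rose in 2, 5 and 2 (20, 18 and 20 lower and 2, 6 and 3 higher adjusted over the list alone). Their adjusted p was 4.41e-10, 3.50e-05 and 1.50e-11, and adjusted p = 0.0359, 0.0810 and 0.0155 with an estimated correlation. Histone genes rose in 7, 8 and 6 of 10 cases (8, 8 and 6 adjusted over the list alone). EGR1 was among the largest falls in KO1 (-1.74) and KO2 (-1.78), and ETV4 in KO1 (-1.78) and KO3 (-1.81). CXCR4 (-1.65), H4C8 (1.56) and ANXA3 (1.52) stood out in KO1, CLIC3 (1.87), VASN (1.86), SSPOP (1.82) and FOS (-1.64) in KO2, and IFIT1 (-1.71) in KO3.

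Some calls among the largest single-pool changes were lost when 1 library was left out, while each kept its sign in all 8 fits. NOMO3, which has near copies, was at 3.25 in KO1 (adjusted p = 0.0166, 0.214 without control replicate 1, log2 fold changes of 2.19 to 7.91 over the fits). RHOF was at -1.72 in KO2 (adjusted p = 0.00795, 0.0624 without KO2 replicate 2 and 0.0620 without control replicate 2, with log2 fold changes of -1.84 to -1.61). In KO3 it was at -1.61 (adjusted p = 0.0135), and its adjusted p was 0.192 without KO3 replicate 1 and 0.0713 and 0.0975 without control replicate 1 or 2, with log2 fold changes of -2.59 to -0.90. Also in KO3, PRRG3 was at 1.89 (adjusted p = 0.00300, 0.0585 without control replicate 2) and KLF15 at 1.87 (0.00332, 0.0587 without control replicate 1), with ranges of 1.53 to 2.46 and 1.78 to 1.94. GPM6A was at 1.79 (adjusted p = 0.0115, 0.101 without KO3 replicate 1, and 0.0845 and 0.106 without control replicate 1 or 2, with a range of 1.54 to 2.04).

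Gene counts per pool were 2107 in KO1 (1008 higher and 1099 lower), 3514 in KO2 (1961 and 1553) and 2402 in KO3 (1085 and 1317). Of 4137 genes called in at least 1 pool, 1552 changed alike in all 3, 688 higher and 864 lower, and 21 changed in opposite directions in a pair of pools. With library totals alone the share of higher genes was 60.2% in place of 47.8% in KO1, 65.1% in place of 55.8% in KO2, 62.5% in place of 45.2% in KO3, and 58.9% in place of 44.3% among the genes changed alike. After GC and length correction that share was 46.9% in KO1, 47.3% in KO2, 46.6% in KO3 and 43.9% among genes changed alike. The pools share the same 2 controls, so their fold changes are not independent. This was simulated with only the spread within groups, which leaves out any other difference between the 2 controls and the pools. Such a difference would also be shared by the pools, so the simulations cannot set it apart from the knockout. In 20 simulations with no true change and shared controls, r between pools averaged 0.511 (highest 0.533), against 0.765 to 0.813 observed. The covariance reached at most 0.0253, against 0.115 to 0.126 observed, and at most 1 gene changed alike. Leaving out 1 library moved these counts by more than 1.5 times. The KO1 count was 3329 without KO1 replicate 1, 826 without control replicate 1 and 1055 without control replicate 2. The KO2 count was 1638 without KO2 replicate 2, 1536 without control replicate 1 and 2128 without control replicate 2. For KO3 the count was 3715 and 3688 without KO1 replicate 1 or 2, 1112 and 1094 without KO3 replicate 1 or 2, and 894 and 1324 without control replicate 1 or 2. Genes changed alike numbered 624 and 881 without control replicate 1 or 2, and 892 and 914 without KO3 replicate 1 or 2.

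The pools parted most clearly in interferon-stimulated genes, a set induced in antiviral defence. In KO2, 22 of 39 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.38, adjusted p = 4.30e-09, adjusted p = 0.0262 with an estimated correlation). In KO3, 27 fell and 1 rose (29 and 1 adjusted over the list alone, median -0.72, adjusted p = 1.37e-22, adjusted p = 0.0121 with an estimated correlation). In KO1, 9 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.22, adjusted p = 0.000643, adjusted p = 0.0556 with an estimated correlation). IFI27 stood at 8.31 ± 0.192 CPM in control, 6.77 ± 0.836 in KO1, 19.5 ± 0.755 in KO2 and 2.69 ± 1.5 in KO3 (n = 2 each). It differed between KO3 and KO2 by -2.78 (SE 0.23, adjusted p = 5.85e-06), DDX60 by -2.13 and IFIT1 by -2.11. These 3 calls held in all 8 fits without 1 library. Antigen presentation genes rose in 9 of 14 cases in KO2 (10 adjusted over the list alone, adjusted p = 0.000715, adjusted p = 0.0966 with an estimated correlation) and did not pass in KO1 (0.469) or KO3 (0.533).

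In the joint test 63 genes differed among the pools, 62 of them highest in KO2, and 26 of the 63 were on the interferon list, against 0.185 expected by chance. Directly compared, 97 genes were lower in KO3 than in KO2, 26 were higher and 1, MED1, lower in KO2 than in KO1, and 3 were lower in KO3 than in KO1. ISG15 (1.72, adjusted p = 0.000705), IFI27 (1.54, 0.00156) and PARP10 (1.46, 0.0357) were the largest rises from KO1 to KO2. The PARP10 call was lost without KO1 replicate 1 (0.221), KO2 replicate 2 (0.755), KO3 replicate 2 (0.0510) or either control (0.103 each). MED1 differed between KO2 and KO1 by -0.46 (adjusted p = 0.0250), and reached 0.269 and 0.169 without KO2 replicate 1 or 2, 0.0510 without KO3 replicate 2 and 0.0660 and 0.0663 without control replicate 1 or 2. The 3 genes lower in KO3 than in KO1 were OAS1 (-0.79, adjusted p = 0.0359), IFI6 (-0.67, 0.0144) and MED1 (-0.64, 0.0138). All 3 calls were lost without KO3 replicate 1 (0.534 for OAS1 and 0.409 for IFI6 and MED1), KO3 replicate 2 (0.303 and 0.155), control replicate 1 (0.120 and 0.0602) or control replicate 2 (0.116 and 0.0592). The 63 became 489 without KO1 replicate 1, 1208 without KO1 replicate 2, 42 without KO2 replicate 1, 27 without KO2 replicate 2, 32 and 35 without KO3 replicate 1 or 2, and 36 without either control.

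**Figure D2:**
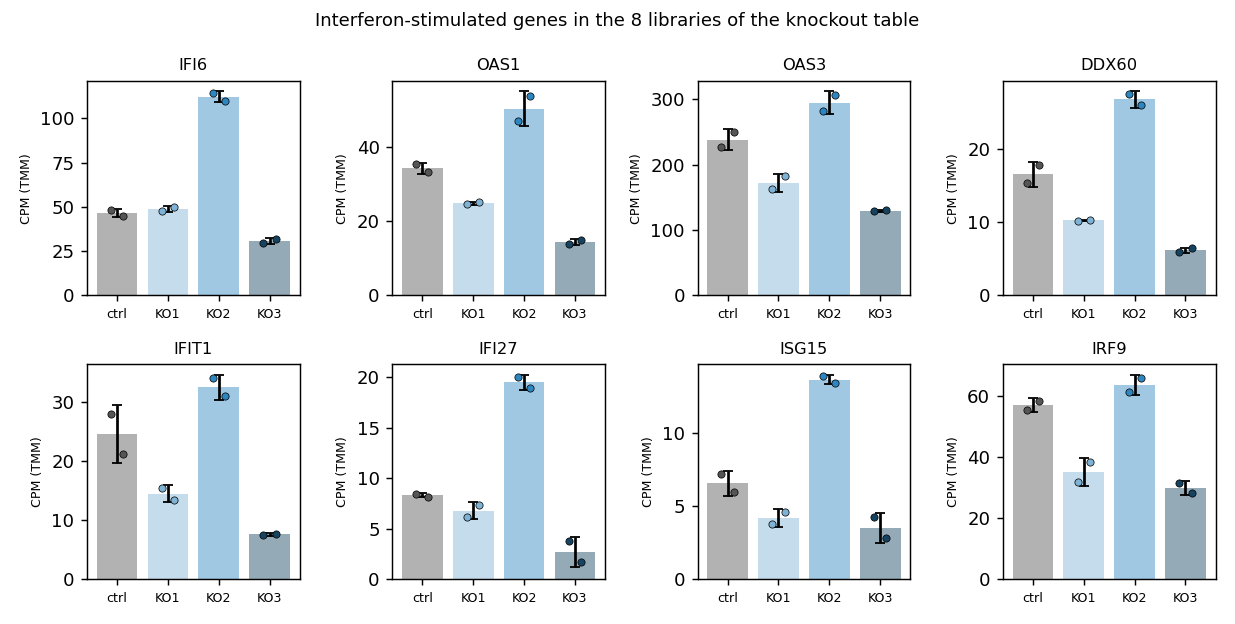
Levels of 8 interferon-stimulated genes in CPM after TMM scaling, per library (points) with the mean and SD of the 2 libraries of each group, in control, KO1, KO2 and KO3. In each gene drawn the mean was highest in KO2 and lowest in KO3, as for IFI27 (19.5 against 2.69 CPM).

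The other comparison asks how gene expression differs between cells with mutant 6KR MED1 and cells with WT MED1. With 6KR, LY6E-DT, a transcript divergent from LY6E, rose 19.8-fold from 0.827 ± 0.314 to 16.4 ± 0.591 CPM (n = 3 each, log2 fold change 4.31, SE 0.19, adjusted p = 2.60e-05). TIMP3 rose from 119 ± 4.27 to 288 ± 2.61 CPM (1.28, SE 0.05, adjusted p = 1.65e-05), and CLEC3A from 55.9 to 130 CPM (1.21, adjusted p = 4.61e-05). IGFBP5, which binds insulin-like growth factors, rose from 8.82 to 24.5 CPM (1.48, adjusted p = 0.000181). Further rises were SGCG (1.81), the imprinted RNA gene H19 (1.46), TARP (1.18, a gene that shares reads with a T cell receptor locus) and EDARADD (1.00). NPY1R, a neuropeptide Y receptor gene that oestrogen induces, fell from 50.7 to 29.7 CPM (-0.77, adjusted p = 0.00119). LAMB1, a laminin gene, fell from 26.3 to 15.5 CPM (-0.76) and SYBU from 33.9 to 20.3 CPM (-0.73). TFF1 rose from 1034 ± 41.0 to 1454 ± 51.7 CPM (0.49, SE 0.05, adjusted p = 0.00340) and HK2, for a hexokinase, from 86.1 to 125 CPM (0.54, adjusted p = 0.00223). Each of these 13 genes kept its call in all 6 fits without 1 library.

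Other large changes were called with all 6 libraries but lost when 1 was left out. SYT10 and AKR1C1, which shares reads with AKR1C2, were at 0.90 and 0.89 (adjusted p = 0.0157 and 0.00962). LINC00052 (-0.83, 0.0116), P2RX2 (-0.81, 0.0240), VASN (-0.79, 0.0241), ENTREP1 (-0.79, 0.0122), IFI44 (-0.77, 0.0287), DGKQ (-0.74, 0.0351) and RFNG (-0.74, 0.0318) completed the largest falls among genes with an official symbol and a mean of at least 5 CPM. XBP1 was at 0.46 (900 ± 102 to 1241 ± 21.4 CPM, adjusted p = 0.0165) and PGR at -0.54 (0.0201), and both calls were lost without any 1 of the libraries other than WT replicate 1. Of 83 named genes that passed, 67 were lost without 6KR replicate 1 (at up to 0.194), 57 without replicate 2 (0.190), 66 without replicate 3 (0.190), 64 without WT replicate 2 (0.161), 51 without WT replicate 3 (0.137) and 0 without WT replicate 1. Of the genes given whatever their result, ESR1 stood at 393 ± 19.9 and 408 ± 18.2 CPM (0.05, adjusted p = 0.618), and GREB1 (-0.09, 0.637), MYC (0.02, 0.886), CCND1 (0.14, 0.128), CDKN1A (0.16, 0.110), MED24 (-0.08, 0.547), SIRT1 (0.02, 0.847) and EP300 (0.37, 0.197) did not pass.

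By gene group, histones, antigen presentation and matrix genes were lower with 6KR and amino acid response and repair genes higher, but none of these list calls held with an estimated correlation. Replication-dependent histone genes, uncertain as single members, fell in 5 of 10 cases (7 adjusted over the list alone, median -0.28, adjusted p = 3.08e-07, adjusted p = 0.163 with an estimated correlation). H2BC12 fell from 77.6 to 49.9 CPM (-0.64). Antigen presentation genes fell in 4 of 16 cases (7 adjusted over the list alone, median -0.26, adjusted p = 3.48e-05, adjusted p = 0.163 with an estimated correlation). HLA-A was at -0.52 (adjusted p = 0.00833, 0.0533 and 0.0601 without 6KR replicate 1 or 3). Interferon-stimulated genes fell in 4 of 41 cases (6 adjusted over the list alone, adjusted p = 6.00e-05, adjusted p = 0.809 with an estimated correlation). ATF4 and amino acid response genes rose in 6 of 31 cases and fell in 0 (11 and 1 adjusted over the list alone, median 0.12, adjusted p = 6.51e-06, adjusted p = 0.163 with an estimated correlation). DNA repair genes had a median of 0.15 with 1 of 30 genes higher (6 adjusted over the list alone, adjusted p = 0.000189, adjusted p = 0.276 with an estimated correlation). Extracellular matrix genes fell in 7 of 23 cases and rose in 1, TIMP3 (11 and 2 adjusted over the list alone, adjusted p = 0.00345, adjusted p = 0.734 with an estimated correlation). COL3A1, a collagen gene, fell from 41.9 to 25.5 CPM (-0.72, adjusted p = 0.00328). It was the single member that fell of 3 fibroblast markers tested (1 adjusted over the list alone, adjusted p = 0.00854, adjusted p = 0.276 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 1 of 33 cases (1 adjusted over the list alone, adjusted p = 0.00854, 0.514 without WT replicate 1, adjusted p = 0.809 with an estimated correlation). RNA polymerase II subunits and pausing factors (2 of 24 lower, 6 adjusted over the list alone) had adjusted p = 0.0438. This reached 0.0501 and 0.121 without 6KR replicate 1 or 3 and 0.0557 without WT replicate 3. Autophagy and lysosome genes (1 of 28 lower, and 4 adjusted over the list alone) had adjusted p = 0.0498. This reached 0.0739 and 0.144 without 6KR replicate 1 or 3 and 0.0716 without WT replicate 1. Both lists had adjusted p = 0.276 with an estimated correlation and 0.452 and 0.449 after GC correction.

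The remaining 28 lists tested did not pass in 6KR against WT. G2/M and mitosis genes had 0 of 35 members called (0 adjusted over the list alone, adjusted p = 0.319) and DNA replication and G1/S genes 1 of 39 (1 adjusted over the list alone, 0.359). Oestrogen-induced genes had 4 of 39 higher and 8 lower (6 and 14 adjusted over the list alone, adjusted p = 0.0851). Adjusted p was 0.775 for Mediator subunits, luminal genes, p53 targets, hypoxia genes, glycolysis enzymes, aryl hydrocarbon receptor targets, nuclear receptors, apoptosis genes, keratins and cell junction genes, and endothelial markers. It was 0.221 for ribosome biogenesis and NRF2 genes, 0.271 for heat shock, endoplasmic reticulum stress and cholesterol genes, 0.319 for neighbours of MED1, and 0.328 for metallothioneins, immediate early genes and acetyltransferases and deacetylases. It was 0.534 for NF-kB genes, 0.576 for fatty acid genes, 0.625 for blood and immune cell markers, 0.736 for basal genes, 0.799 for ribosomal proteins and 0.842 for YAP and TGF-beta targets. The median, mean and test differed in sign for the Mediator, G2/M, ribosomal protein, p53, NF-kB, immediate early, YAP and TGF-beta, aryl hydrocarbon receptor, nuclear receptor, keratin and endothelial lists.

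**Figure D3:**
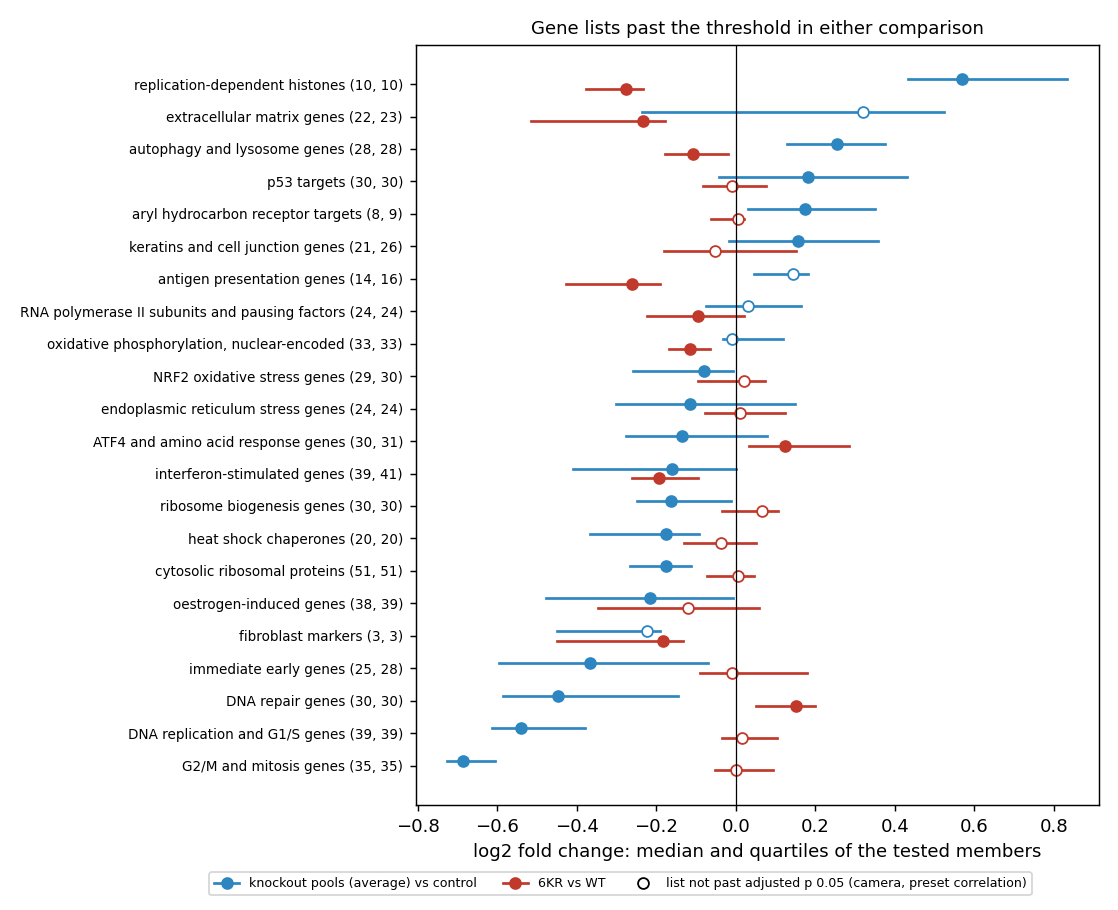
Median (point) and quartiles (line) of the log2 fold changes of the tested members of each gene list that passed in either comparison, with the numbers of members tested in the knockout and 6KR tables in parentheses and filled points for lists past the threshold by camera with the preset correlation. G2/M and mitosis genes lie at -0.69 in the knockout pools and near 0 with 6KR, and histones lie at 0.57 and -0.28.

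In all, 638 of 14839 genes (4.30%) passed, 247 higher and 391 lower, 20 and 19 of them by at least 2-fold. All 638 had no overlap between the groups, against 30.6% of tested genes and 10% by chance. Passing the threshold with 3 libraries per group favours genes without overlap, so this is not separate support. After correction for GC content and length 770 passed and 50% of them were higher, against 38.7% without it. At an adjusted p of 0.01, 60% of 75 genes were higher. WT replicate 1 stood apart from the other 5 libraries on the second principal component (25.6 against -14.7 to 7.98), and without it 2859 genes passed, all 638 among them. The count was 40, 83 and 49 without 6KR replicate 1, 2 or 3, and 68 and 133 without WT replicate 2 or 3. Higher genes made up 62.5%, 54.2%, 61.2%, 61.8% and 47.4% of these in the same order. They made up 43.3% without WT replicate 1. The direction with more genes thus differed between the fits without 1 library. Of 83 named genes that passed, 15 did so in all 6 such fits and all 83 kept their sign. After GC and length correction 21 of the 83 fell short of the threshold, and with replicate number as a block 34 did.

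Set side by side, the knockout and 6KR changes ran mostly in opposite directions. Of 319 genes called in both comparisons, 278 (87.1%) had opposite signs, against 166 if signs were independent among these genes. Genes lower in the knockout pools and higher with 6KR numbered 106, against 33.5 if calls in the 2 tables were independent, among them TIMP3 (-1.42 and 1.28), SGCG (-1.25 and 1.81), TFF1 (-1.10 and 0.49), CLEC3A (-0.85 and 1.21) and H19 (-1.06 and 1.46). MED1 was another (-0.30 and 0.69), with calls lost without control replicate 2 (0.0844) or 6KR replicate 1 or 3 (0.0603 and 0.0556). MED1 is the gene altered by design, so its signs are not a response like those of the other genes. Another 172 were higher in the pools and lower with 6KR, against 53.8, such as SYBU (0.73 and -0.73) and LAMB1 (0.54 and -0.76). The same direction was shared by 27 lower genes, including COL3A1 (-0.68 and -0.72) and NPY1R (-0.84 and -0.77), and by 14 higher genes, against 53.7 and 33.6. Of 5 lists that passed in both comparisons, 4 had opposite directions, namely histones, autophagy and lysosome, ATF4 and DNA repair genes. Interferon-stimulated genes were lower in both, although they rose in KO2. With an estimated correlation none of the 5 passed in 6KR and only histones did in the pools. The oestrogen-induced list, which holds TFF1, leaned lower in both, with medians of -0.22 in the pools and -0.12 with 6KR. With 6KR 4 of its 39 members were higher and 8 lower. Its adjusted p there was 0.0851 by camera, 0.323 with an estimated correlation and 0.0228 by fry.

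Across 13293 genes tested in both tables, fold changes correlated with r = -0.29 and rho = -0.32, and r = -0.40 over genes with a mean of at least 5 CPM, where genes are not independent replicates. The 1862 genes raised in the knockout pools had a median of -0.13 with 6KR, and 25.2% of them were above 0 (fry p = 0.0195, adjusted p = 0.0390 over the 2 sets, adjusted p = 0.122 by camera with an estimated correlation). After correction of the 6KR fold changes for GC content and length this median was -0.0667 (adjusted p = 0.00362 by fry in limma). The 1858 lowered genes had a median of 0.06, and 68.9% were above 0 (adjusted p = 0.0514 by fry, 0.122 by camera with an estimated correlation). By fry in limma, the call on raised genes was lost without 6KR replicate 1 (adjusted p = 0.0680), 2 (adjusted p = 0.110) or 3 (adjusted p = 0.0850) and without WT replicate 2 (adjusted p = 0.102) or 3 (adjusted p = 0.0959). It was also lost with replicate number as a block (adjusted p = 0.145), library totals alone (adjusted p = 0.0514) and the sets called in KO3 (adjusted p = 0.0565). Without WT replicate 1 both sets passed (adjusted p = 0.00219 for raised and adjusted p = 0.00353 for lowered genes).

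**Figure D4:**
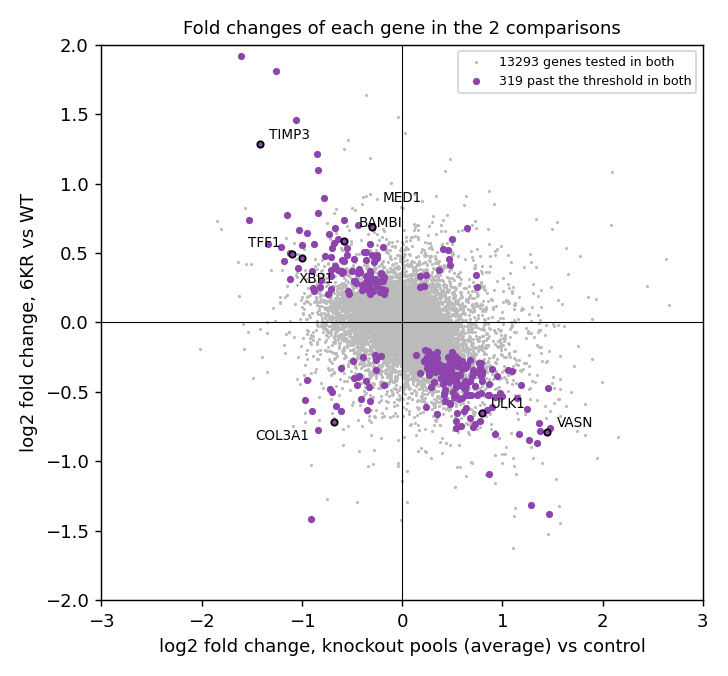
Log2 fold change of each of 13293 genes in the knockout pools (average) against control on the horizontal axis and in 6KR against WT on the vertical axis, with the 319 genes called in both comparisons coloured and 3 genes beyond the axes. Most coloured genes (278 of 319) lie where the signs differ, among them TIMP3 and TFF1. MED1 also lies there, but it is the gene altered by design, and its count does not separate ectopic from endogenous transcripts.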

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

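The comparison of the pools was planned, while the test of where the KO1 libraries lie was chosen after the MED1 levels were seen and before its own result. The effect against control differed among the 3 pools for 18 named genes, by the joint test of the pools, and values below are log2 fold changes in KO1, KO2 and KO3 in that order with the adjusted p of that test. In simulated data 11.4% of the calls of this test were unchanged genes.

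Interferon-stimulated genes made up most of them. IFI6 had 0.06, 1.27 and -0.61 (2.05e-08), with 46.6 CPM in control, 48.7 in KO1, 112 in KO2 and 30.7 in KO3. OAS1 had -0.47, 0.55 and -1.26 (9.60e-07), and OAS3 had -0.46, 0.31 and -0.88 (9.60e-07). DDX60 had -0.69, 0.70 and -1.43 (1.94e-06), IFIT1 -0.77, 0.40 and -1.71 (5.49e-06), and IFITM1 -0.46, 0.28 and -0.93 (5.49e-06). For IFI27 the values were -0.31, 1.23 and -1.55 (1.47e-05), for IRF9 -0.71, 0.16 and -0.92 (4.24e-05), and for ISG15 -0.66, 1.05 and -0.87 (7.74e-05). PARP10 had -0.42, 1.04 and -0.84 (0.00579), IFI44 -0.46, 0.90 and -2.22 (0.0179) and SP110 0.18, 0.48 and -0.10 (0.0230).

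Outside that group, HLA-C had -0.10, 0.59 and -0.40 (0.000714). The heat shock genes HSPA1A (0.16, 0.68 and -0.02, 0.00817) and HSPA1B (0.22, 0.62 and 0.05, 0.0264) are near copies that share reads. NCOR2, a corepressor gene of nuclear receptors, had 0.33, 0.74 and 0.24 (0.0274), and ULK1 had 0.61, 1.20 and 0.58 (0.0318).

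MED1 itself differed among the pools (0.06, -0.40 and -0.58, 0.00138), because its transcript was not lower in the libraries labelled KO1. If a KO1 library were a mislabelled control, it would lie near 0 on an axis from control (0) to the mean of KO2 and KO3 (1), over 2924 genes called alike in both of those pools in a fit without KO1. The KO1 libraries lay at 0.786 and 0.974, which argues against a mislabelled control. The controls (-0.02 and 0.02) average 0 and KO2 (1.0 and 1.1) with KO3 (0.95 and 0.96) average 1 by construction. The genes were picked against these same controls, so another control could lie somewhat above 0, by an amount not tested. An edit that changes the MED1 protein and leaves the transcript level alone, or a pool with some unedited cells, may remain, since no value here measures the edit or the protein.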

How the results depend on the processing

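The correction for GC content and length, the fits on library totals, the changed scaling, filters and camera tests of the knockout-responsive sets, and for named genes the filter, the fits of 2 groups and those without a pool were chosen after the data were seen. Of 268 results for single genes, 4281 values under alternatives stayed on the same side of the threshold, 564 fell short of it, 5 newly passed, and 0 changed sign among those past the threshold before or after. Every list that passed kept its direction under the alternatives run on lists. Small changes could be missed, as 58.2% of simulated 1.5-fold changes were recovered in the pool average and 73.1% in 6KR against WT. Fewer genes were changed in these simulations than were called in the real data, so recovery there may differ. Each fit had 4 residual degrees of freedom, and how far these or depth set the limit was not tested. Deviations of libraries with the same replicate number correlated at r of -0.03 to 0.17 in the knockout table and -0.09 to 0.11 in the 6KR table. With replicate number as a block the pool average count rose from 3720 to 4310, and the 6KR count fell from 638 to 211. Whether replicate numbers pair the samples is thus not settled.

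Stricter limits leave fewer genes by construction. With an adjusted p of 0.01 the counts were 2127 for the pool average (3720 in the report), 1062 for KO1 (2107), 1954 for KO2 (3514), 1209 for KO3 (2402), 836 for genes changed alike (1552), 32 for the pool differences (63) and 75 for 6KR (638). With a log2 fold change of at least 1 they were 193, 157, 302, 203 and 75 in the same order, and 39 for 6KR. DESeq2 gave 1385 for KO1, 1560 for KO3 and 1144 for 6KR, and it left 1547 and 2302 genes without an adjusted p in the knockout and 6KR tables. It called 2564 of the 3720 genes and 621 of the 638. In the simulated pool average DESeq2 recovered 46.3% of 1.5-fold changes (edgeR 58.2%), and 2.80% of its calls were unchanged genes (edgeR 7.51%). In simulated 6KR against WT both recovered 73.1%, and 14.1% of DESeq2 calls were unchanged genes (edgeR 4.42%). GC and length correction gave 3407 for KO1, 3662 for KO3, 2442 changed alike and 126 pool differences. It gave 14 lists in the knockout pools (17 in the report) and 14 in 6KR (10). Without a filter 516 genes differed among the pools, and with only KO3 and control in the fit 3963 passed. For DESeq2, the correction, the filter and the smaller fit, the cause was not tested.

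With the replicate block 184 genes differed among the pools and 211 passed in 6KR, with 4310 for the pool average, 2664, 4054 and 3014 for KO1, KO2 and KO3, 1947 changed alike, and 17 and 10 lists. With an estimated correlation 4 of 17 lists passed in the knockout pools and 0 of 10 in 6KR (fry gave 24 and 8), and the cause was not tested. Size factors of the other kind shifted the median of all genes by -0.02 and 0.01 and library totals by 0.05 and -0.00.

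Without 1 library each, counts ran from 1364 to 5119 for the pool average, 826 to 3329 for KO1, 1536 to 4757 for KO2, 894 to 3715 for KO3, 624 to 2326 changed alike, 27 to 1208 pool differences and 40 to 2859 for 6KR. Lists ran from 16 to 17 and from 8 to 14.

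The knockout-lowered genes in 6KR, at a median of 0.0575 with adjusted p = 0.0514 by fry in limma, passed with the 200 smallest p (0.0920, adjusted p = 0.00552), the GC correction (0.0540, adjusted p = 0.0124), the other size factors (0.0654, adjusted p = 0.0318), camera at the preset correlation (0.0575, adjusted p = 1.65e-09) and genes changed alike (0.0668, adjusted p = 0.0287). They also passed with library totals (0.0540, adjusted p = 0.0155), a mean of 5 CPM (0.0571, adjusted p = 0.0289), no filter (0.0598, adjusted p = 0.0424), and sets from KO1 (0.0628, adjusted p = 0.0189) or KO2 (0.0640, adjusted p = 0.0402). They did not with the replicate block (0.0600, adjusted p = 0.145), sets from KO3 (0.0491, adjusted p = 0.0797) or camera at an estimated correlation (0.0575, adjusted p = 0.122). Without 1 library each the median ran from 0.0408 to 0.0970. The raised genes, at -0.13 with adjusted p = 0.0390, lost the call with camera at an estimated correlation (-0.13, adjusted p = 0.122), library totals (-0.14, adjusted p = 0.0514), sets from KO3 (-0.11, adjusted p = 0.0565) and the replicate block (-0.13, adjusted p = 0.145). They kept it with the GC correction, which halved the median (-0.0667, adjusted p = 0.00362). They ran from -0.15 to -0.11 without 1 library each. The p here are adjusted over the 2 sets, a choice made after the unadjusted p had been seen. Unadjusted, the only call that differed was that of raised genes with sets from KO3, which passed. The cause of these changes was not tested.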

Other observations

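The tests of GC content and length, of the fits without WT replicate 1 and of the MED1 amount in the 6KR cells were chosen after their results were seen, and the sum over histone genes and the splits of the 6KR and WT libraries before theirs.

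Several genes moved in the knockout pools within lists that did not pass. Among cell survival genes, the anti-apoptotic BCL2 fell by 0.85 and BIRC5 by 0.52, while BCL2L1 rose by 0.43. BCL2 is also on the oestrogen-induced list and BIRC5 on the G2/M list, both of which passed, so these falls are not a separate signal. In cholesterol metabolism INSIG1 was at -0.60, ACAT2 at -0.57 and the LDL receptor gene LDLR at -0.36, while TM7SF2 was at 0.62. The respiratory chain gene COX6C fell from 629 ± 57.2 CPM (n = 2) to 416 ± 40.7 CPM (n = 6, -0.60, adjusted p = 3.03e-05). The hypoxia-related EPAS1 rose by 0.74 while STC1 fell by 0.48, and the laminin gene LAMA3 rose by 0.70. Each of these kept its call in all 8 fits without 1 library.

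The opposite signs of the knockout and 6KR changes (r = -0.29 across genes) were set against 3 explanations. A shared trend on GC content or gene length would bring r close to 0 once removed from 1 side. With only the 6KR fold changes corrected and the knockout ones not, r was -0.24, which argues against that trend as the whole cause. It may account for part, since the correction brought the median of the knockout-raised genes in 6KR from -0.13 to -0.0667. Dependence on WT replicate 1, which stood apart, would do the same when it was left out, and r was then -0.35, the lowest of the 6 fits without 1 WT or 6KR library (-0.35 to -0.21). The amount of MED1 transcript, 0.69 higher on the log2 scale with 6KR, was lower in KO2 and KO3 but not in KO1 (0.06). The genes called in KO1 still had opposite medians with 6KR, at -0.11 for raised and 0.0628 for lowered genes. KO1 shares its controls with KO2 and KO3, and MED1 protein was not measured. These medians therefore cannot decide whether the amount of MED1 accounts for the opposite signs. In the 6KR libraries the amount and the mutation cannot be told apart because every one has both.

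In the knockout pools histone genes rose while replication genes fell. A trend on GC content or length would bring the histone median near 0 once removed, but it was 0.51 after the correction, against 0.57 before, and still passed (adjusted p = 5.26e-09, and 0.0491 with an estimated correlation). Reads passed among the 10 tested histone genes would leave their sum alone. The sum rose by 0.70 on the log2 scale, with 388 CPM in the lowest knockout library and 266 in the highest control. Reads passed to or from histone genes outside the list would change the sum, so this cannot exclude them. Histone transcripts of this kind mostly lack a polyadenylated tail, so a change in the share that carries one may remain alongside a change in histone expression, and neither was tested.

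The 6 WT and 6KR libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. As many as the real 638 genes came from 1 split, the real one (highest other 0), and as many as 10 lists from 1 (highest other 9). A median of the knockout-raised genes as far from 0 as the real one (size 0.132) came from 1 split (highest other 0.0832), and of the knockout-lowered genes (0.0575) from 3 (highest other 0.0741). A correlation with the knockout changes as large as the real one (size 0.292) came from 3 splits (highest other 0.347), and the others were splits that put WT replicate 1 with 2 of the 6KR libraries.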
